A study of Homo sapiens with 12 samples.

How the data were processed

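Messenger RNA was measured in 12 tumours grown from Huh-7 cells, an established human hepatocellular carcinoma line, under the skin of BALB/c nude mice. The cell line label gives Huh-7 for all 12, but the titles name Huh-8, Huh-9 and Huh-10 for the CS2164, IR and CS2164_IR samples, and which is right was not tested. The mice were 6 weeks old, and treatment began when the tumours averaged 150 to 200 mm3. There were 4 groups of 3 libraries: control (vehicle), CS2164 (10 mg/kg per day by oral gavage), IR (2 Gy per day in 10 fractions) and the combination of both, written CS2164_IR. CS2164 is an oral kinase inhibitor, also called chiauranib, which acts on Aurora kinase B, the VEGF receptors, PDGFRA, KIT and CSF1R. The libraries were made from poly-A RNA with a protocol that does not mark the strand, so reads from overlapping genes on opposite strands cannot always be assigned.

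The deposited table gives a read count and an FPKM per gene and library for 19988 protein-coding genes named by Ensembl identifier. Per the submitters' notes, the authors aligned reads to GRCh38 with HISAT2 2.1.0 and counted them with HTSeq 0.9.1. The annotation release, and whether mouse reads were removed, are not given in the sources used here. The count columns hold whole numbers, and these deposited counts were used for every test. The FPKM values of the authors equal the count divided by gene length and by the library's total over this table, which was checked. They served here only to obtain gene length. Symbols were attached to 19941 of the genes.

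Genes were kept with the filterByExpr function of edgeR 4.0.16 (R 4.3.3), which left 13521 tested genes. Libraries were scaled by TMM, and CPM below are the cpm values of edgeR after that scaling. One quasi-likelihood model with a coefficient per group and no other term was fitted to all 12 libraries with robust estimation. Standard errors were derived from the fold change and its F statistic. p-values were adjusted by the Benjamini-Hochberg method within each comparison, with a threshold of 0.05. There were 5 comparisons of group pairs, the effects of CS2164 and of IR each averaged over the other treatment, and their interaction, 8 in all. Higher and lower always refer to the group named first.

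Before the data were examined, 30 gene lists were fixed. For DNA repair and the cell cycle they were homologous recombination and Fanconi repair, nonhomologous end joining, excision and mismatch repair, damage checkpoint signalling, p53 targets, mitosis, DNA replication with the G1/S transition, and replication-dependent histones. For the tumour environment they were hypoxia, glycolysis, interferon-stimulated genes, MHC class I presentation, cytokines, secreted angiogenesis factors, extracellular matrix with epithelial-mesenchymal transition, and the known kinase targets of CS2164. For liver and stress they were hepatocyte genes, fetal liver and liver cancer markers, cholesterol biosynthesis, the unfolded protein response, NRF2 targets, apoptosis regulators, early stress genes and mitochondrially encoded genes. The last 6 held markers of other cells: endothelial, fibroblast and pericyte, macrophage, lymphoid, skin with muscle and fat, and erythroid. Lists with at least 5 tested members, 27 of them, were tested with camera of limma 3.58.1 on log2 CPM with a prior count of 2, a preset correlation of 0.01 between genes, and adjustment over the 27 lists.

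The rule for named genes was also fixed then. For each pair of groups it took the 6 largest rises and the 6 largest falls that passed the threshold, had at least 1 CPM in the higher group and kept all 3 libraries of one group above all 3 of the other. It added up to 3 passing members of each list by adjusted p, or up to 2 members that did not pass. The averaged effects took 4 in each direction, and a comparison with too few passing genes took the 5 with the lowest p. AURKB, FLT1, KDR, FLT4, PDGFRA, KIT, CSF1R, CDKN1A, MDM2, ALB and AFP were always looked up. Some genes that the rule named in one comparison are also given in another, a choice made after their values were seen.

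Alternatives fixed beforehand were RLE and upper-quartile scaling, no filter, a minimum mean of 1 CPM, the replicate number as a block, limma voom, DESeq2 1.42.0, a fit of the compared groups alone, a 2-fold minimum, each library left out in turn, and for lists an estimated correlation and fry. A correction for each library's trend over GC content and gene length (spline with 4 degrees of freedom, GENCODE annotation of GRCh38), a fit without 2 libraries that stood apart, and an exact permutation of list scores were chosen after seeing the data. In tests on simulated counts with known changes, 2-fold changes were recovered in 64.2% to 79.1% of genes for the 5 pairs of groups and 4-fold changes in 89.4% to 95.5%, but 1.5-fold changes in only 13.4% to 22.4%. For the interaction 2.99% were recovered at 1.5-fold, 37.3% at 2-fold and 87.9% at 4-fold. All gene totals include 4 genes whose own results are not reported here. The depth was 12886607 to 16890346 counts per library, and counting error alone bounds a gene with no reads at 3 counts, 0.178 to 0.233 CPM. p-values measure the spread between these 12 libraries. The labels do not say that each came from a separate animal, and they name no batch.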

Results

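Transcript levels of human protein-coding genes were measured by poly-A RNA sequencing in Huh-7 xenograft tumours from 4 groups of 3 libraries: control, CS2164, IR and CS2164_IR. The control libraries held 13780587, 16691525 and 15944875 counts. The CS2164 libraries held 16597727, 13981180 and 16119311 counts, the IR libraries 14951032, 16060801 and 13551105, and the CS2164_IR libraries 12886607, 16890346 and 15937125. Fold changes are given on the log2 scale with their standard error, and levels as mean ± SD of CPM, with n = 3 libraries per group throughout. Floors cover counting error only. Positions refer to GRCh38.

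Few counts came from marker genes of other cell types. Human markers of endothelial, fibroblast, macrophage, lymphoid, skin, muscle, fat and red blood cells together took at most 0.119% of any library. Host cells in these tumours are of mouse, and how mouse reads were handled is not stated, so counts of these markers, those of fibroblasts, pericytes and macrophages below included, may hold mouse reads. Of the genes for the kinases that CS2164 is known to act on, AURKB and PDGFRA were expressed in the tumours. FLT1 and KDR, which encode VEGF receptors, had 0 counts in each of the 12 libraries, which allows up to 0.178 to 0.233 CPM. FLT4 had 2 reads in 1 CS2164_IR library and 0 elsewhere, KIT had at most 4 reads and CSF1R at most 9 reads in a library. The first principal component of the 500 most variable genes held 23.2% of their variance and the second 19.9%. Of all libraries, control replicate 2 and CS2164 replicate 1 lay farthest from the mates of their own group, with a mean Spearman correlation to them of 0.979 and 0.973, while those mates correlated at 0.994 with each other. CS2164_IR replicate 1 correlated at 0.986 with its mates, which correlated at 0.993 with each other. Mitochondrially encoded genes took 7.82% ± 0.991 of the counts in control, 5.596% ± 0.412 in CS2164, 8.78% ± 1.08 in IR and 9.25% ± 1.35 in CS2164_IR.

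**Figure D1:**
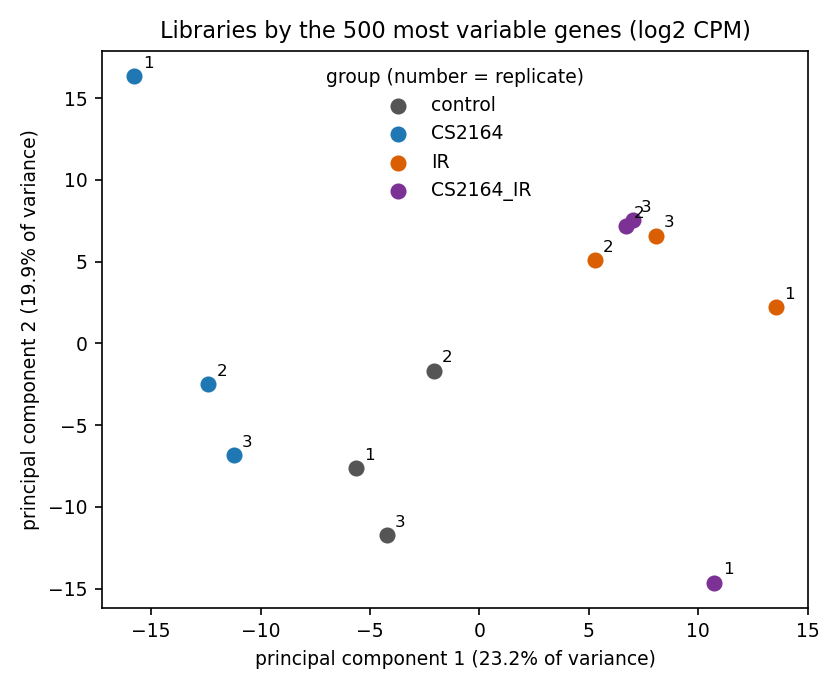
Each point is 1 of the 12 libraries, placed by its score on the first component (horizontal axis, 23.2% of the variance) and the second (vertical axis, 19.9%) of the log2 CPM of the 500 most variable tested genes, with colour for the group. The libraries of a group do not form tight clusters. On the first component all unirradiated libraries lie below 0 (-15.8 to -2.08) and all irradiated libraries above 0 (5.28 to 13.6). CS2164 replicate 1 and CS2164_IR replicate 1 lie farthest from their mates on these axes, and control replicate 2 lies nearer to its own.

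The comparison of CS2164 with control asks what the inhibitor alone changes in the tumours. FN1, which encodes the matrix protein fibronectin (ENSG00000115414, chromosome 2, 215360440 to 215436172), rose by 1.08 ± 0.18, from 7810 ± 1107 to 16516 ± 2485 CPM. LRP1, a large endocytic receptor, rose by 1.70 ± 0.22. PTTG1, the securin that holds back chromosome separation (ENSG00000164611, chromosome 5, 160421822 to 160428744), fell from 100 ± 32.6 to 47.4 ± 6.86 CPM, a log2 change of -1.08 ± 0.18. AURKB, the mitotic kinase that CS2164 acts on, fell from 75.7 ± 2.70 to 54.4 ± 3.81 CPM, a change of -0.48 ± 0.13 with an adjusted p of 0.022, a call that ended without control replicate 2, CS2164 replicate 2 or CS2164 replicate 3.

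Mitosis genes were lower with CS2164. Of 62 tested members 22 fell, 1 rose and 39 did not pass (27 fell and 1 rose when adjusted over the list alone), with a median of -0.37. The median was -0.27 without CS2164 replicate 1 and -0.24 with the GC and length trends removed, and the mean list score was -0.582, 0.0116 and 0.0236 in CS2164 replicates 1 to 3 against 0.200, 0.2195 and 0.339 in control. CCNB1, the cyclin of mitotic entry, changed by -0.83 ± 0.14, UBE2C, which marks mitotic proteins for destruction, by -0.69 ± 0.15, and BIRC5, a partner of Aurora kinase B, by -0.74 ± 0.16. In camera the list was lower than other genes with an adjusted p of 2.19e-07, and adjusted p = 0.766 with an estimated correlation. The replication and G1/S list did not pass (median -0.08, adjusted p of 0.596): 6 of 52 members fell, among them ORC6 by 0.76 ± 0.15, and 2 rose, among them MCM2, a subunit of the replicative helicase, by 1.12 ± 0.22.

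The list of matrix and epithelial-mesenchymal genes was higher. Of 38 tested members 10 rose, 1 fell and 27 did not pass (12 and 1 when adjusted over the list alone), with a median of 0.43, an adjusted p of 0.00201, and adjusted p = 0.297 with an estimated correlation. Beside FN1, LAMC1, a laminin chain, rose by 0.77 ± 0.14 and ITGA5, part of the fibronectin receptor, by 0.74 ± 0.16. The 10 also held CDH1, the epithelial cadherin that is lost in an epithelial-mesenchymal transition, and the 1 that fell was VIM, the filament vimentin that is gained in it, both looked at after their values were seen. Of 14 fibroblast and pericyte markers, which may hold mouse reads, 6 rose and none of the 8 others passed (6 over the list alone), with a median of 0.47, an adjusted p of 0.0212, and adjusted p = 0.297 with an estimated correlation. That list did not pass with the GC and length trends removed (adjusted p of 0.107) or without the 2 distant libraries, control replicate 2 and CS2164 replicate 1 (adjusted p of 0.0643). The 6 included CSPG4, a pericyte proteoglycan, by 1.15 ± 0.24 and COL1A1, a chain of type I collagen, by 1.60 ± 0.48, the latter at only 1.26 ± 0.0406 CPM. The call of COL1A1 ended when control replicate 1, control replicate 2 or any of the CS2164 replicates was left out, and also with the GC and length trends removed. All markers of that cell type together took 0.0452% to 0.0613% of the counts in the CS2164 libraries and 0.0314% to 0.0383% in control. Of 18 glycolysis genes 2 rose and 16 did not pass (1 over the list alone), with a median of 0.45, an adjusted p of 0.045, and adjusted p = 0.848 with an estimated correlation. That list did not pass without CS2164 replicate 1 (median 0.11, adjusted p of 0.542), control replicate 1 (0.103), control replicate 3 (0.318) or IR replicate 3 (0.0519), without the 2 distant libraries (0.189), with the trends removed (0.263) or with the replicate block (0.0573). One of the 2, PFKL, the liver phosphofructokinase, rose by 0.76 ± 0.19.

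The 13 mitochondrially encoded genes were lower, with 4 falls and 9 that did not pass (7 falls over the list alone), a median of -0.45, an adjusted p of 0.00889, and adjusted p = 0.766 with an estimated correlation. MT-CO3, a subunit of cytochrome c oxidase, changed by -0.78 ± 0.19. Removing the trends over GC content and gene length turned the median of this list to 0.05, and without control replicate 3 the adjusted p was 0.128. The cholesterol list did not pass as a set (median 0.15, adjusted p of 0.225), but 7 of its 24 members rose and 1 fell, with CYP51A1, an enzyme of sterol synthesis, at 1.43 ± 0.29. The hypoxia list did not pass either (median 0.23, adjusted p of 0.147), with 8 of 43 rising, EGLN1, an oxygen-sensing hydroxylase, by 1.08 ± 0.20, and 1 falling. Of 27 NRF2 targets 6 fell and none rose (adjusted p of 0.192, and 0.0248 without the 2 distant libraries). IGF2, a growth factor of fetal liver, rose by 1.34 ± 0.27.

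The DNA repair lists, the subject of the series title, did not pass as sets with CS2164 alone. Of 47 homologous recombination and Fanconi genes 5 fell, such as UBE2T, the Fanconi ubiquitin-conjugating enzyme, by 0.69 ± 0.17, and 1 rose, TOP3A, by 0.66 ± 0.14 (median -0.18, adjusted p of 0.225). Of 19 end-joining genes 2 rose and 2 fell (median -0.23, adjusted p of 0.225), with PRKDC, the DNA-dependent protein kinase, at 0.65 ± 0.16 and SHLD3, a shieldin subunit, at -1.40 ± 0.29. With the GC and length trends removed UBE2T stood at -0.02 and SHLD3 at -0.60, and neither passed (0.948 and 0.161). Of 40 excision and mismatch repair genes 3 rose and 2 fell (median -0.01, adjusted p of 0.933), with XPC, which recognises damage, at 0.68 ± 0.18 and POLB, the gap-filling polymerase, at -0.98 ± 0.20. Of 29 checkpoint genes 1 fell (median -0.13, adjusted p of 0.356). Of 34 p53 targets 4 rose and 4 fell (median -0.03, adjusted p of 0.806), among the falls TRIAP1 at -1.19 ± 0.21 and RPS27L at -0.84 ± 0.17. CDKN1A, the p53-induced cell cycle inhibitor, stood at 20.4 ± 5.02 CPM in control and 29.2 ± 2.68 in CS2164, a change of 0.52 ± 0.18 that did not pass (adjusted p of 0.0509).

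The largest rises with all libraries separated were MAGEL2 (2.58 ± 0.71), ACAD11, DCHS1, a large cadherin (2.01 ± 0.32), DUOX2, EHD3 and HSPG2, which encodes the basement membrane proteoglycan perlecan (1.92 ± 0.37). In control replicates 1 to 3 MAGEL2 stood at 0.426, 0.126 and 0.248 CPM, ACAD11 at 0.355, 0 and 0.373 and EHD3 at 0.497, 0.126 and 0.186. Several of these levels lie below or near the counting floor of 0.178 to 0.233 CPM. The largest falls were TAS2R14, PDE8B, EEF1E1, a factor of the tRNA synthetase complex (-2.01 ± 0.40), DYNLT2B, HINT2 and ADAM32. Each of these falls ended under 1 CPM in every CS2164 library. ACAD11, TAS2R14, PDE8B, HINT2, SHLD3, XPC, MCM2, RPS27L and LRP1 overlap another expressed gene, so part of their reads may belong to it. EEF1E1, DYNLT2B, CYP51A1, IGF2 and PDGFRA overlap other listed genes on the same strand that had 0 reads. How reads in such overlaps were counted is not stated. The counts of these genes, in all comparisons, may therefore hold only part of their reads. Without CS2164 replicate 1 the change of MAGEL2 was 1.645 (adjusted p of 0.141) and that of DUOX2 0.94 (0.128), and ACAD11, EHD3, DYNLT2B, HINT2 and ADAM32 did not pass either (0.0651 to 0.133). Without control replicate 2 the same genes except DUOX2, and PDE8B, did not pass (up to 0.159).

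By the edgeR test 1409 genes were higher and 1260 lower with CS2164, 2669 in all, and 4728 had an unadjusted p under 0.05. Libraries were fully separated for 36.4% of genes, against 10% by chance. That 10% is the expectation for each gene, here and below. Genes are not independent, so a trend shared by libraries can raise the share, and its spread over other splits was not measured. Across genes the change rose with GC content (Spearman rho 0.453) and with gene length (rho 0.245), and the genes called higher had a median length of 7623 bases against 3980 for those called lower. With the GC and length trends removed 1078 genes were called higher and 1097 lower, 2175 in all, and 1292 of the 2669 were still called in the same direction. Of the genes examined singly in this comparison, 51 of 76 kept their call then and 39 of 77 without the 2 distant libraries. Without control replicate 2 alone 33 of 77 kept it, and with the compared groups alone 23 of 74. The count was 963 without control replicate 2 and CS2164 replicate 1, 621 without control replicate 2, 1676 without CS2164 replicate 1, 285 with the compared groups alone, 320 at 2-fold, and 1131 higher against 1543 lower with upper-quartile scaling.

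**Figure D2:**
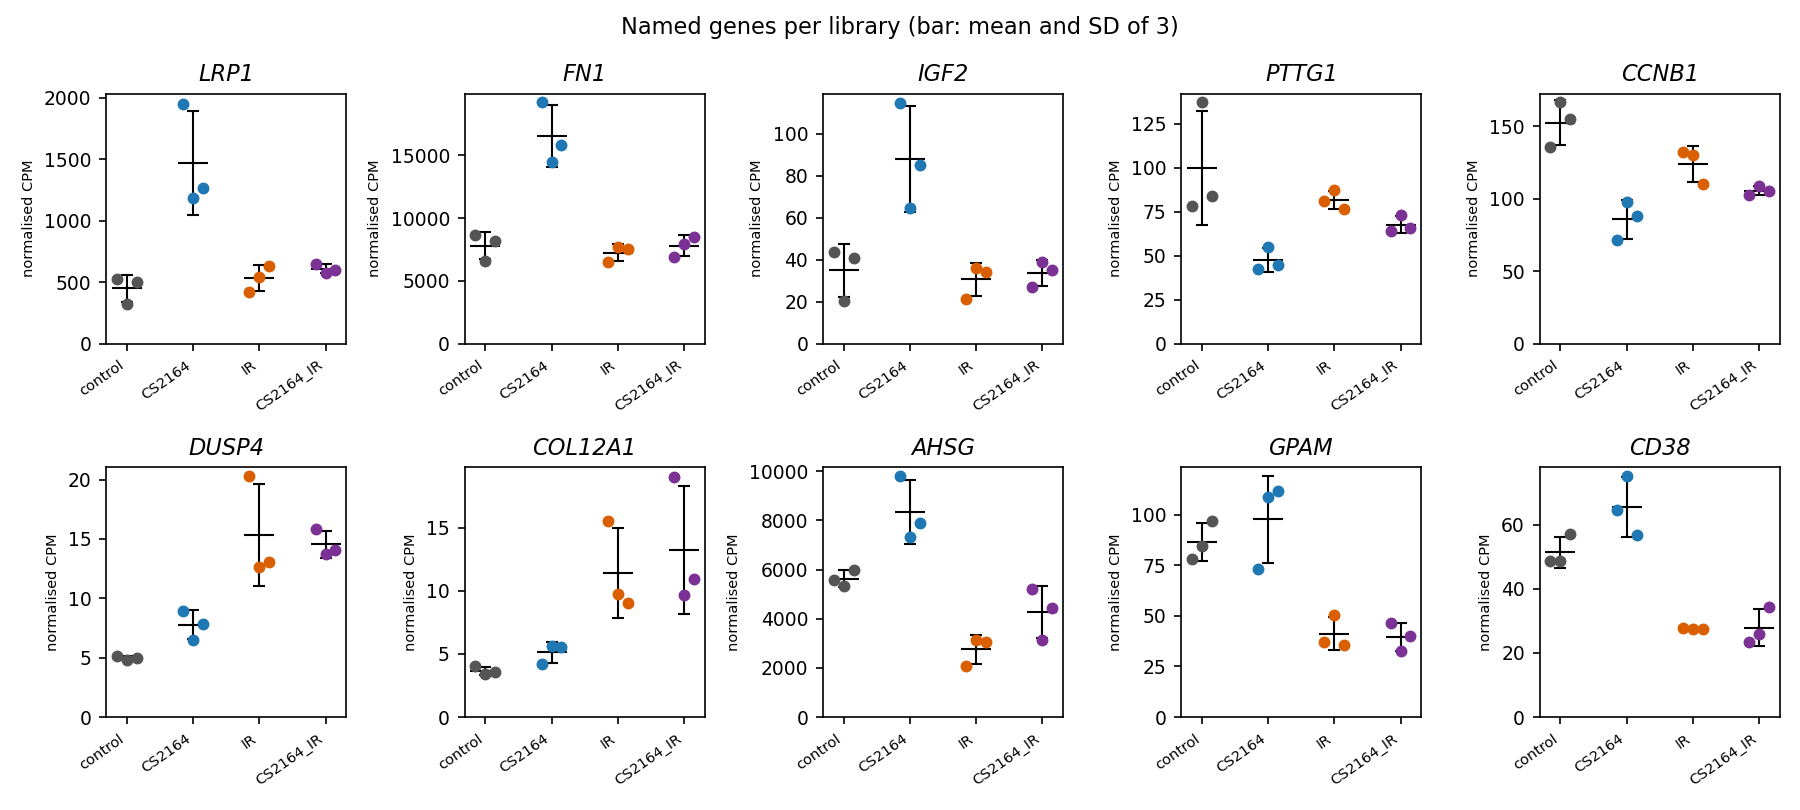
Levels in CPM of 10 genes (1 panel each, linear axis) in the 12 libraries, with a point per library and a bar for the mean of 3 and its SD in each group. LRP1, FN1 and IGF2 are highest in the CS2164 group, while DUSP4 and COL12A1 are higher, and GPAM and CD38 lower, in both irradiated groups than in control.

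The comparison of IR with control asks what radiation alone left in the tumours. DUSP4, a phosphatase that acts on MAP kinases (ENSG00000120875, chromosome 8, 29333064 to 29350668), rose by 1.63 ± 0.21, from 4.97 ± 0.136 to 15.3 ± 4.29 CPM. FOSL1, a member of the AP-1 transcription factor, rose by 3.16 ± 0.46, from 0.374 ± 0.106 to 3.37 ± 1.27 CPM, and COL12A1, a matrix collagen, by 1.64 ± 0.28. AHSG, the plasma protein fetuin-A made by hepatocytes, fell from 5632 ± 342 to 2750 ± 578 CPM.

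Hepatocyte genes were lower: 2 of 39 fell and 37 did not pass (10 fell when adjusted over the list alone), with a median of -0.38, an adjusted p of 1.5e-07, and adjusted p = 0.244 with an estimated correlation. The second of them, NR1H4, the bile acid receptor, changed by -0.94 ± 0.20. Of 24 cholesterol genes 1 fell (6 over the list alone), with a median of -0.24, an adjusted p of 0.000838, and adjusted p = 0.0528 with an estimated correlation. It was INSIG1, the sterol-regulated brake on cholesterol synthesis, at -0.60 ± 0.13. None of 62 mitosis genes passed alone, also over the list alone, and the list was lower with a median of -0.20, an adjusted p of 0.000838, and adjusted p = 0.665 with an estimated correlation. Without IR replicate 3 the adjusted p of the mitosis list was 0.067.

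Replication-dependent histones were higher, with 26 of 29 above 0, a median of 0.56 and an adjusted p of 2.67e-07, and adjusted p = 0.0528 with an estimated correlation. None passed over all genes and 6 rose over the list alone. H2BC5 stood at 31.6 ± 2.15 CPM in control and 50.4 ± 3.00 in IR, a change of 0.68 ± 0.17 that did not pass. The libraries were made from poly-A RNA, so histone transcripts without a poly-A tail were not tested here or in the comparisons below. Of 26 early stress genes FOSL1 alone rose (4 over the list alone), with a list median of 0.22, an adjusted p of 0.00116, and adjusted p = 0.324 with an estimated correlation. Of 38 matrix and epithelial-mesenchymal genes COL12A1 alone rose (5 over the list alone), with a median of 0.28, an adjusted p of 0.00988, and adjusted p = 0.244 with an estimated correlation. The matrix list did not pass without control replicate 2 (0.0696), IR replicate 1 (0.0926) or the 2 distant libraries (0.0756). Of 14 fibroblast and pericyte markers 1 rose, MCAM at 0.80 ± 0.17 (5 over the list alone), with a median of 0.33, an adjusted p of 0.00287, and adjusted p = 0.0601 with an estimated correlation. ADAMTS1, a matrix protease that restrains vessel growth, rose by 0.92 ± 0.14 and NRP2, a receptor for VEGF and semaphorins, by 1.09 ± 0.23.

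No member of the homologous recombination, end-joining, excision repair, checkpoint or p53 lists passed over all genes, and none of these lists passed (adjusted p of 0.141, 0.897, 0.489, 0.897 and 0.636). With the GC and length trends removed the homologous recombination list was higher with an adjusted p of 0.0016, while it had 0.31 without the 2 distant libraries, 0.165 with the replicate block and 0.765 with an estimated correlation. CDKN1A stood at 18.9 ± 2.54 CPM in IR (change -0.11 ± 0.18) and MDM2, another p53 target, at 43.9 ± 4.64 against 49.3 ± 2.70 in control. The other large rises were SLC4A3 (2.30 ± 0.39), F2RL2 and ACTN3 (1.75 ± 0.28), and the other large falls IFIT1, an interferon-induced gene (-1.17 ± 0.24), HPR, PKLR, KANK4 and DAO. F2RL2, IFIT1, HPR, PKLR and MCAM overlap another expressed gene, and HPR reads may come from its near copy HP.

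By edgeR 28 genes were higher and 31 lower, 59 in all, and 2129 had an unadjusted p under 0.05. Libraries were separated for 26.3% of genes against 10% by chance, and the change rose with GC content (rho 0.438). The count was 0 without IR replicate 1, 5 without control replicate 2, 9 without IR replicate 3, and 11 and 12 without control replicates 1 and 3. It was 20 to 28 without CS2164 replicate 2, IR replicate 2 or CS2164_IR replicates 2 or 3. Without CS2164 replicate 1, a library of neither compared group, the count was 458. It was 20 with the replicate number as a block, 22 with voom, 117 without a filter, 138 with the compared groups alone, 340 with DESeq2, 351 with the GC and length trends removed (108 higher and 243 lower) and 445 without the 2 distant libraries.

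The combination against control asks what both treatments together changed. COL12A1 (ENSG00000111799, chromosome 6, 75084326 to 75206051) rose by 1.84 ± 0.28, from 3.66 ± 0.342 to 13.2 ± 5.07 CPM. GPAM, which starts triglyceride synthesis (ENSG00000119927, chromosome 10, 112149864 to 112215377), fell from 86.4 ± 9.38 to 39.6 ± 6.95 CPM, a change of -1.13 ± 0.19. CD38, an enzyme that consumes NAD, changed by -0.88 ± 0.16, and AKR1B10, an aldo-keto reductase often high in liver cancer, by -1.07 ± 0.19. SLC4A3 (2.27 ± 0.39) and ACTN3 (1.92 ± 0.28) rose, as in IR alone, and TPPP3, a tubulin-binding protein, rose by 3.54 ± 0.60. TNFRSF25 and ATG9B, both overlapped by other expressed genes, rose too, and DDC, ARHGAP19 and LCP1 fell.

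Mitosis genes were lower as a set: 59 of 62 lay below 0, none passed over all genes and 18 fell when adjusted over the list alone, with a median of -0.42, an adjusted p of 1.85e-14, and adjusted p = 0.361 with an estimated correlation. Of 38 matrix and epithelial-mesenchymal genes COL12A1 alone rose (6 over the list alone), with a median of 0.36, an adjusted p of 7.65e-05, and adjusted p = 0.128 with an estimated correlation. Of 29 histones 1 rose, H2BC5 by 1.05 ± 0.17 (8 over the list alone), with a median of 0.42, an adjusted p of 0.000117, and adjusted p = 0.13 with an estimated correlation. Fibroblast and pericyte markers (median 0.44, adjusted p of 0.00348, and adjusted p = 0.128 with an estimated correlation) and macrophage markers (median 0.64, adjusted p of 0.0308, and adjusted p = 0.145 with an estimated correlation) were higher as sets, with 0 of 14 and 0 of 10 passing over all genes and 5 and 4 over the list alone. Macrophage markers took 0.0156% to 0.0292% of the counts in CS2164_IR and 0.0158% to 0.0221% in control. The macrophage list did not pass without control replicate 1, control replicate 3, CS2164_IR replicate 1 or CS2164_IR replicate 3 (adjusted p of 0.0512 to 0.0879).

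The early stress genes (median 0.25, adjusted p of 0.0046, and adjusted p = 0.41 with an estimated correlation) and mitochondrially encoded genes (median 0.25, adjusted p of 0.0343, and adjusted p = 0.694 with an estimated correlation) were higher as sets with no member passing over all genes and 3 and 1 over the list alone. Without CS2164_IR replicate 3 their adjusted p was 0.0581 and 0.0743, and the mitochondrial list also did not pass without control replicate 1 (0.34) or CS2164_IR replicate 1 (0.389). The angiogenesis list was higher (median 0.19, adjusted p of 0.0397, and adjusted p = 0.145 with an estimated correlation), with 3 of 24 rising over the list alone. Its 1 member that passed over all genes, NRP2 (1.16 ± 0.23), is a membrane receptor and not a secreted factor, and its call ended without any 1 of the control or IR libraries or CS2164_IR replicate 1 or 3 (up to 0.201). This list did not pass without control replicate 1, control replicate 3, CS2164_IR replicate 2 or CS2164_IR replicate 3 (adjusted p of 0.0693 to 0.158) or with the replicate block (0.0519). Unfolded protein response genes were lower (median -0.28, adjusted p of 0.000692, and adjusted p = 0.37 with an estimated correlation), with 0 of 28 passing and 5 falling over the list alone. NRF2 targets were lower (median -0.27, adjusted p of 0.000996, and adjusted p = 0.512 with an estimated correlation), with AKR1B10 alone of 27 falling (3 over the list alone). No repair, checkpoint or p53 list passed (adjusted p of 0.227 to 0.85).

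By edgeR 20 genes were higher and 6 lower, 26 in all, and 2218 had an unadjusted p under 0.05. All 26 had the same sign in IR alone against control, a comparison that shares the controls. The change rose with GC content (rho 0.480), and libraries were separated for 26.4% of genes against 10% by chance. The count was 0 without control replicate 2 or control replicate 3, 9 without control replicate 1 or CS2164_IR replicate 1, 10 without CS2164_IR replicate 3, 14 without IR replicate 2 and 436 without CS2164 replicate 1. It was 13 with the compared groups alone, 39 with the replicate block, 96 without a filter, 296 with the GC and length trends removed (94 higher and 202 lower, so the balance turned), 316 with DESeq2 and 417 without the 2 distant libraries.

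**Figure D3:**
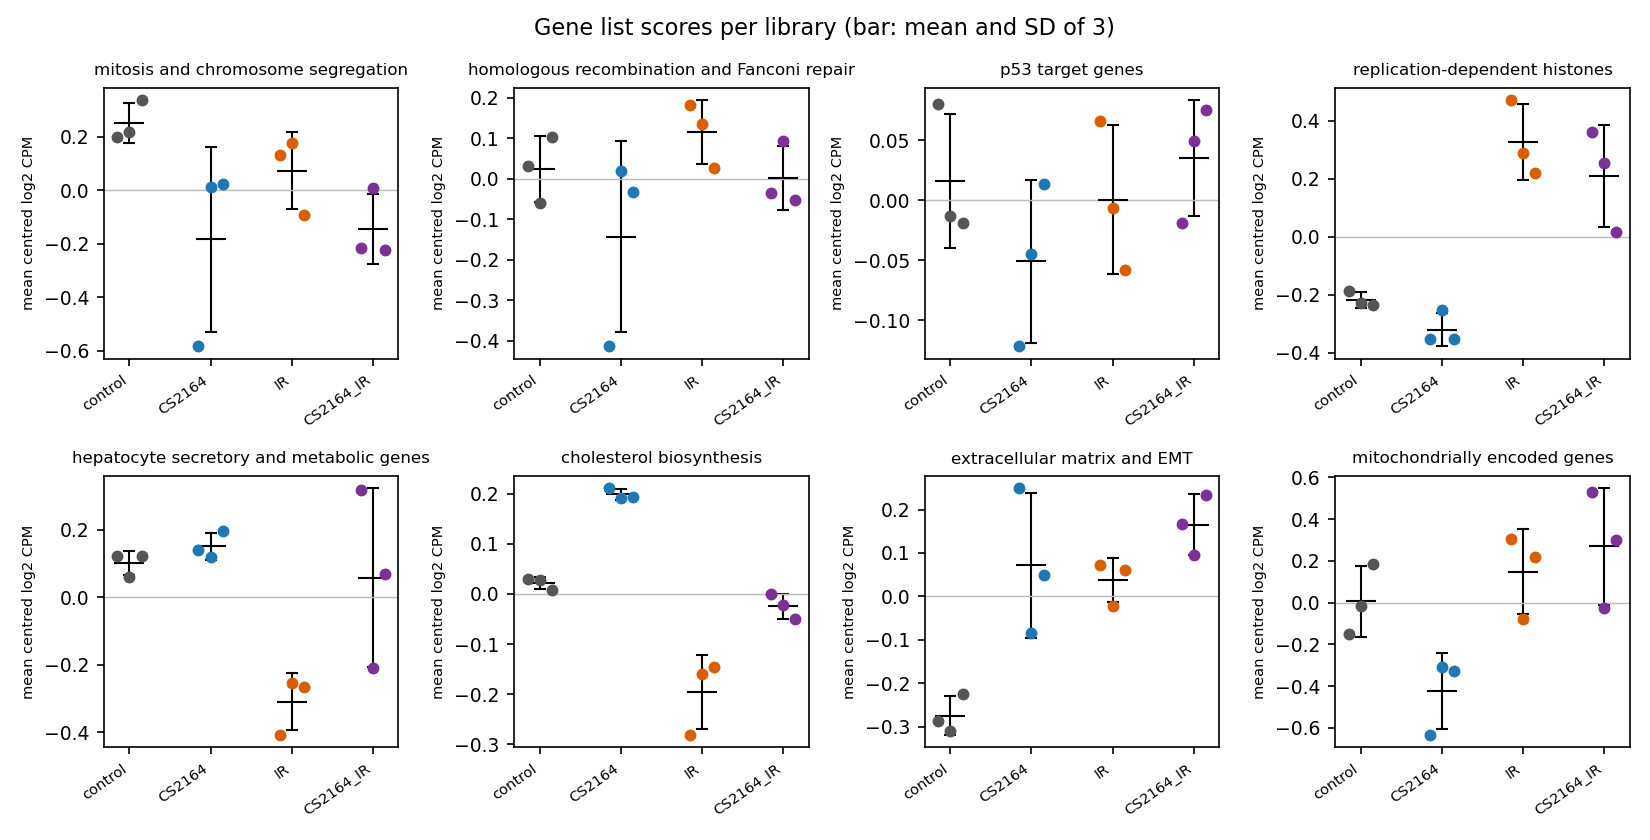
Scores of 8 gene lists (mean log2 CPM of the members relative to the mean of all libraries, vertical axis) in each library, with a point per library and a bar for the mean of 3 and its SD. The mitosis score is lower in the 3 treated groups than in control, with list medians of -0.37, -0.20 and -0.42, and the histone score is higher in both irradiated groups.

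The combination against IR asks what CS2164 adds to radiation. By edgeR no gene passed, where 331 had an unadjusted p under 0.05, and limma voom and DESeq2 also called 0. The lowest p-values, none of them passing, belonged to TPPP3 (2.36 ± 0.54), ACY3 (1.00 ± 0.27), GBP3, an interferon-induced GTPase (1.17 ± 0.32), ADGRD1 (0.88 ± 0.24) and SERPINC1, which encodes antithrombin (0.99 ± 0.27). AURKB stood at 66.3 ± 6.94 CPM in the combination and 73.7 ± 8.41 in IR, and ALB, the albumin gene, at 19112 ± 5619 and 13854 ± 613. Libraries were separated for 9.50% of genes, against 10% by chance. The 95% interval of the change excluded a 2-fold difference for 11227 genes, 83.0% of those tested.

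As sets, hepatocyte genes were higher in the combination than in IR, with 38 of 39 above 0, a median of 0.38, an adjusted p of 1.31e-16, and adjusted p = 0.0787 with an estimated correlation. Without CS2164_IR replicate 1 the median was 0.20. All 24 cholesterol genes lay above 0, with a median of 0.17 and an adjusted p of 5.58e-06, and this was the 1 list of the comparison that held with an estimated correlation (adjusted p = 0.0201). Skin, muscle and fat markers were higher (7 of 8 above 0, median 0.28, adjusted p of 0.00217, and adjusted p = 0.0787 with an estimated correlation), as were interferon-stimulated genes (median 0.08, adjusted p of 0.0152, and adjusted p = 0.238 with an estimated correlation) and matrix and epithelial-mesenchymal genes (median 0.16, adjusted p of 0.0152, and adjusted p = 0.333 with an estimated correlation). Without CS2164_IR replicate 1 these 3 lists did not pass (adjusted p of 0.0871, 0.225 and 0.0529), and without CS2164_IR replicate 3 or IR replicate 2 the interferon list (0.117 and 0.352) and the matrix list (0.0727 and 0.186) did not. The interferon list also did not pass without control replicate 3, CS2164 replicate 2, CS2164 replicate 3 or IR replicate 3 (0.0638 to 0.0936). The skin, muscle and fat score was 0.436, -0.221 and 0.0535 in CS2164_IR replicates 1 to 3 and -0.295, -0.139 and -0.150 in IR.

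Lower as sets were mitosis genes (59 of 62 below 0, median -0.23, adjusted p of 1.11e-13, and adjusted p = 0.348 with an estimated correlation), replication genes (43 of 52 below 0, median -0.10, adjusted p of 2.64e-05), NRF2 targets (24 of 27 below 0, median -0.21, adjusted p of 4.1e-05), homologous recombination and Fanconi genes (37 of 47 below 0, median -0.11, adjusted p of 0.00101), checkpoint genes (22 of 29 below 0, median -0.10, adjusted p of 0.00981) and unfolded protein response genes (24 of 28 below 0, median -0.08, adjusted p of 0.00691). For those after mitosis the adjusted p = 0.398 with an estimated correlation. Without CS2164_IR replicate 1 the NRF2, checkpoint and unfolded protein lists did not pass (0.0529, 0.0529 and 0.374), and without CS2164_IR replicate 3 the replication, recombination and checkpoint lists did not (0.0817, 0.0579 and 0.0817), nor did the checkpoint list without IR replicate 1 (median -0.06, 0.0894). In none of these lists did a member pass over all genes. Adjusted over the list alone, 1 skin, muscle and fat marker rose and no member of the other lists passed.

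The combination against CS2164 asks what radiation adds to the inhibitor. SPINK1, a trypsin inhibitor high in some liver cancers, rose by 1.71 ± 0.28, from 131 ± 28.8 to 428 ± 217 CPM. APOB, the main protein of the lipoproteins that liver secretes (ENSG00000084674, chromosome 2, 21001429 to 21044073), fell from 6847 ± 1257 to 2615 ± 114 CPM, a change of -1.39 ± 0.18. FN1 (-1.08 ± 0.18), LAMC1 (-0.81 ± 0.14) and IGF2 (-1.39 ± 0.27), all higher with CS2164 alone than in control, were lower in the combination than with CS2164 alone. Both of these comparisons rest on the same 3 CS2164 libraries, whose shared deviations enter them with opposite signs. VIM, the mesenchymal filament vimentin, rose by 0.87 ± 0.16.

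Of the 13 mitochondrially encoded genes 10 rose (12 over the list alone), MT-CO3 by 0.97 ± 0.20, with a median of 0.69, an adjusted p of 5.89e-06, and adjusted p = 0.734 with an estimated correlation. With the GC and length trends removed the adjusted p was 0.131. Of 29 histones 3 rose (4 over the list alone), H1-2 by 0.94 ± 0.18 and H2BC5 by 1.00 ± 0.17, with a median of 0.55, an adjusted p of 0.00094, and adjusted p = 0.327 with an estimated correlation; with the trends removed it was 0.594. Of 24 cholesterol genes 5 fell (9 over the list alone), with a median of -0.17, an adjusted p of 0.00707, and adjusted p = 0.251 with an estimated correlation. Glycolysis genes (1 of 18 fell, 1 over the list alone, median -0.49, adjusted p of 0.00094, and adjusted p = 0.846 with an estimated correlation) and hypoxia genes (2 of 43 fell, 2 over the list alone, median -0.25, adjusted p of 0.00319, and adjusted p = 0.846 with an estimated correlation) were lower, but without the 2 distant libraries their adjusted p was 0.234 and 0.647, without CS2164 replicate 1 it was 0.167 and 0.499, and without CS2164_IR replicate 1 it was 0.179 and 0.809. NDRG1, a hypoxia-induced gene, fell by 1.12 ± 0.29. Early stress genes were higher with 1 of 26 rising (1 over the list alone), a median of 0.36, an adjusted p of 0.019, and adjusted p = 0.846 with an estimated correlation. The early stress list did not pass without CS2164 replicate 2, CS2164 replicate 3, CS2164_IR replicate 2 or CS2164_IR replicate 3 (adjusted p of 0.0544 to 0.302).

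The repair lists again held both directions: SHLD3 rose by 1.54 ± 0.29, PRKDC fell by 0.76 ± 0.16 and PARP1, the sensor of strand breaks, by 0.57 ± 0.13, while the homologous recombination, end-joining and excision lists did not pass (adjusted p of 0.241, 0.647 and 0.661). Of 25 cytokines 4 rose (4 over the list alone), with IL18 at 1.84 ± 0.45 and CXCL8, the neutrophil attractant interleukin 8, at 1.20 ± 0.26 (list adjusted p of 0.0903, and 0.0172 without the 2 distant libraries). PLK2, a stress-induced kinase and p53 target, rose by 1.08 ± 0.23. MKI67, the proliferation marker Ki-67, fell by 0.91 ± 0.22, while the mitosis list as a whole did not pass (median -0.03, adjusted p of 0.988, and 0.0355 without the 2 distant libraries). The largest separated rises were MROH2B (3.27 ± 0.66), ITGB1BP2, TPPP3 (3.10 ± 0.58), CNN1 (2.97 ± 0.60), AGR3 and LHFPL3. The largest falls were HCAR3 (-2.20 ± 0.40), ANGPTL8, a liver hormone that limits lipoprotein lipase (-2.08 ± 0.47), NPTX2, HCAR2, NTN3 and TTBK1. HCAR2 and HCAR3 are near copies, and ANGPTL8 lies within another expressed gene, so their reads may be shared.

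By edgeR 511 genes were higher and 799 lower, 1310 in all, and 3775 had an unadjusted p under 0.05, with libraries separated for 32.3% of genes against 10% by chance. The change fell with gene length (rho -0.291), and the genes called lower had a median length of 7887 bases against 3788 for those called higher. The count was 310 without CS2164_IR replicate 3, 355 without CS2164_IR replicate 1, 841 to 854 without CS2164 replicate 2, CS2164 replicate 3 or CS2164_IR replicate 2, and 2049 without control replicate 2. It was 192 at 2-fold, 834 with the compared groups alone, 2537 with the trends removed and 3265 without the 2 distant libraries, and upper-quartile scaling gave 750 higher and 614 lower.

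**Figure D4:**
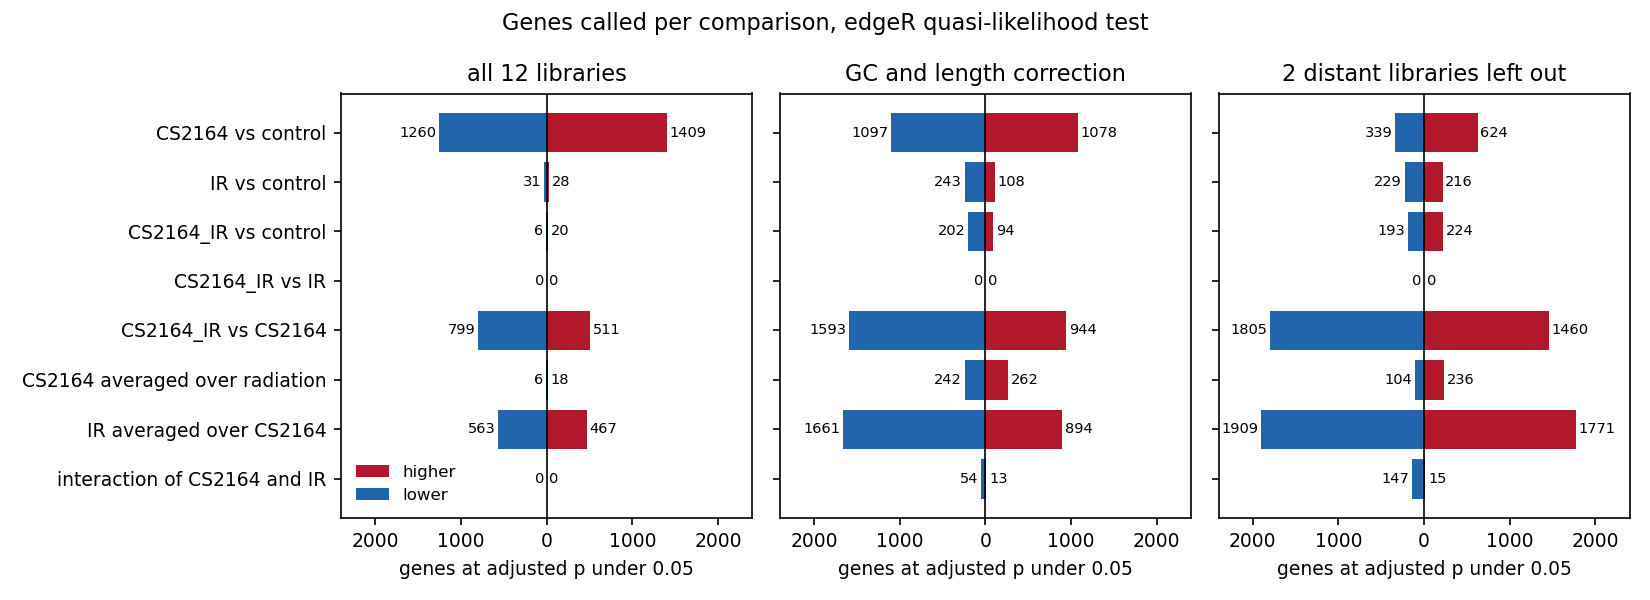
Number of genes called at an adjusted p under 0.05 in each of the 8 comparisons (rows), higher to the right of 0 and lower to the left. The panels show all 12 libraries (left), the GC and length trends removed (middle) and the fit without the 2 distant libraries (right). CS2164 against control gave 2669, 2175 and 963 genes, CS2164_IR against CS2164 gave 1310, 2537 and 3265, and CS2164_IR against IR gave 0 in each panel.

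Averaged over radiation, SEZ6L2 (1.00 ± 0.16), LRP1 (0.95 ± 0.15), HAVCR1 (0.94 ± 0.16) and C3, the central complement protein (0.88 ± 0.16), rose with CS2164, while CRLF3 (-0.81 ± 0.14), ZNF121, PTTG1 (-0.68 ± 0.13) and CDKN3, a phosphatase of cell cycle kinases, fell. In the direction of their averaged call, the 24 genes called here had a median change of 1.04 without radiation and of only 0.23 with it. Of 62 mitosis genes 2 fell, PTTG1 and CCNB1 (-0.53 ± 0.10), and 30 over the list alone, with a median of -0.31, an adjusted p of 8.77e-14, and adjusted p = 0.466 with an estimated correlation. Of 24 cholesterol genes 2 rose (7 over the list alone), with a median of 0.17, an adjusted p of 0.00338, and adjusted p = 0.15 with an estimated correlation. The list of 38 matrix and epithelial-mesenchymal genes was higher (median 0.32, adjusted p of 0.000149, and adjusted p = 0.15 with an estimated correlation), with 10 rising over the list alone. Its 1 member that passed over all genes, CDH1 (0.64 ± 0.11), is not a matrix gene but the epithelial cadherin, which is lost in an epithelial-mesenchymal transition. Its call ended with the replicate block and without control replicate 2 or 3, CS2164 replicate 3, any 1 of the IR libraries or CS2164_IR replicate 1 or 3 (up to 0.179). Of 39 hepatocyte genes F5, coagulation factor V, rose by 0.56 ± 0.10 (4 over the list alone; median 0.22, adjusted p of 0.000152, and adjusted p = 0.501 with an estimated correlation).

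The homologous recombination and Fanconi list was lower by a median of 0.14 with an adjusted p of 0.0145, and adjusted p = 0.616 with an estimated correlation, 33 of 47 members below 0 and none passing, also over the list alone. Without CS2164 replicate 1 or control replicate 3 it did not pass (0.114 and 0.0659). NRF2 targets (adjusted p of 0.00338, 4 falling over the list alone), checkpoint genes (adjusted p of 0.0473, none over the list alone), replication genes (adjusted p of 0.0381, 1 falling over the list alone) and unfolded protein response genes (adjusted p of 0.0381, none over the list alone) were lower with no member passing over all genes, and with an estimated correlation the adjusted p = 0.719 for replication genes and 0.616 for the other 3. With RLE scaling the checkpoint list did not pass (0.052). With the trends removed the checkpoint, replication and unfolded protein lists did not (0.0748, 0.102 and 0.124), and without the 2 distant libraries the checkpoint and replication lists did not (0.129 and 0.075). The NRF2 list lost its call without CS2164 replicate 3 (0.078), and the unfolded protein list without CS2164 replicate 2 or 3, control replicate 2 or CS2164_IR replicate 1 (0.0917 to 0.152). The checkpoint and replication lists lost theirs without control replicate 1, CS2164 replicate 1, IR replicate 2, CS2164_IR replicate 1 or CS2164_IR replicate 3, the former also without control replicate 3 or IR replicate 1 and the latter without CS2164 replicate 3 (0.0593 to 0.246). Fibroblast and pericyte markers were higher with an adjusted p of 0.0381 (2 rising over the list alone), and adjusted p = 0.253 with an estimated correlation, and did not pass with the trends removed (0.13), without the 2 distant libraries (0.129) or without control replicate 2, CS2164 replicate 1, IR replicate 2 or CS2164_IR replicate 2 (0.0572 to 0.0633). By edgeR 18 genes were higher and 6 lower, 24 in all, and 3103 had an unadjusted p under 0.05. The count was 0 without control replicate 2 or 3, CS2164 replicate 3, any 1 of the IR libraries or CS2164_IR replicate 3, 6 and 8 without CS2164_IR replicates 2 and 1, 47 and 210 without CS2164 replicates 1 and 2, and 432 without control replicate 1. Other settings gave 1 at 2-fold, 4 with the replicate block, 13 with voom or upper-quartile scaling, 333 without a filter, 340 without the 2 distant libraries, 504 with the trends removed (262 higher and 242 lower) and 1015 with DESeq2.

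Averaged over CS2164, FOSL1 (2.13 ± 0.31), DUSP4 (1.26 ± 0.15), COL12A1 and TIMP1, an inhibitor of matrix proteases (0.98 ± 0.18), rose with IR, while APOB (-1.07 ± 0.12), AHSG, CPS1, the first enzyme of the urea cycle (-1.53 ± 0.25), and GPAM (-1.19 ± 0.13) fell. The other large changes were rises of MROH2B, ATG9B and TPPP3 and falls of ANGPTL8, HCAR3 and SLC22A7. In these poly-A libraries all 29 histones lay above 0 and 9 rose (15 over the list alone), H2BC5 by 0.84 ± 0.12. The list had a median of 0.54 and an adjusted p of 9.41e-08, which held with an estimated correlation (adjusted p = 0.0396). Whether all histone transcripts or only those with a poly-A tail rose was not tested. Of 24 cholesterol genes 5 fell (7 over the list alone), HMGCS1, an early enzyme of the pathway, by 0.46 ± 0.10, with a median of -0.21 and an adjusted p of 2.28e-05, which also held (adjusted p = 0.0278 with an estimated correlation). Of 39 hepatocyte genes 8 fell (10 fell and 1 rose over the list alone), with a median of -0.24, an adjusted p of 6.35e-05, and adjusted p = 0.389 with an estimated correlation. Of 13 mitochondrially encoded genes 3 rose (10 over the list alone), with a median of 0.38, an adjusted p of 2.28e-05, and adjusted p = 0.389 with an estimated correlation.

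Of 26 early stress genes 3 rose (7 over the list alone; adjusted p of 0.000253, and adjusted p = 0.389 with an estimated correlation), and of 25 cytokines 3 rose (4 over the list alone), IL18 by 1.30 ± 0.31 (adjusted p of 0.0479, and adjusted p = 0.389 with an estimated correlation). The cytokine list did not pass with the trends removed (0.137) or without any 1 of 8 libraries (0.0832 to 0.181), those other than control replicates 1 and 2, CS2164 replicate 1 and IR replicate 2. Glycolysis (median -0.32, adjusted p of 0.00727, none passing, also over the list alone) and hypoxia genes (median -0.23, adjusted p of 0.00863, with 2 of 43 falling, 2 also over the list alone) were lower, each with adjusted p = 0.753 with an estimated correlation, and had an adjusted p of 0.596 and 0.847 without the 2 distant libraries. Without control replicate 2, CS2164 replicate 1 or CS2164_IR replicate 1 neither passed (0.0714 to 0.413), and with the trends removed hypoxia did not (0.075). Of 47 homologous recombination and Fanconi genes 2 rose (2 over the list alone), XRCC3 by 0.42 ± 0.11 and EME1 by 0.51 ± 0.14, with a median of 0.10, an adjusted p of 0.0441, and adjusted p = 0.728 with an estimated correlation. This list did not pass without the 2 distant libraries (0.677), control replicate 2, CS2164 replicate 1, IR replicate 1, IR replicate 2, CS2164_IR replicate 1 or CS2164_IR replicate 2 (0.0609 to 0.451). PARP1 changed by -0.40 ± 0.09 and MUTYH, which repairs oxidised bases, by 1.04 ± 0.25. Both of those recombination genes and MUTYH overlap another expressed gene.

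By edgeR 467 genes were higher and 563 lower, 1030 in all, and 3374 had an unadjusted p under 0.05. The count was 445 to 677 when a library other than control replicate 2, CS2164 replicate 1 or IR replicate 2 was left out, 1596 without control replicate 2 and 2397 without CS2164 replicate 1. It was 110 at 2-fold, 1558 with DESeq2, 2555 with the trends removed (894 higher and 1661 lower) and 3680 without the 2 distant libraries, and upper-quartile scaling gave 626 higher and 423 lower.

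No gene passed the test of the interaction of CS2164 and IR by edgeR, where 2732 had an unadjusted p under 0.05 and the smallest adjusted p was 0.0839. Voom also called 0, DESeq2 called 656, the GC and length correction 67, no filter 60 and the fit without the 2 distant libraries 162. The lowest p-values belonged to IGF2R, the receptor that clears IGF2 (-1.39 ± 0.23), SALL2 (-1.17 ± 0.21), NOMO3, 1 of several near copies (-1.78 ± 0.32), NOTCH2 (-1.20 ± 0.22) and ADAMTS9 (-1.47 ± 0.27). IGF2R stood at 200 ± 43.0 CPM in control, 481 ± 56.1 in CS2164 and 221 ± 21.6 in CS2164_IR.

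Across genes, which are not independent replicates, the CS2164 effect without radiation correlated weakly with that with radiation (Pearson r 0.0829, Spearman rho 0.0928), and 53.1% of genes had the same sign. The 2669 genes called with CS2164 alone had a median change of 0.67 there and of 0.02 in the same direction in the combination against IR, and 1481 of them (55.5%) kept their sign. The correlation was -0.0221 without a filter and -0.0517 without IR replicate 1. The IR effect without and with CS2164 had r = 0.222 and rho = 0.133, with the same sign in 52.3% of genes, and r was 0.346 with the trends removed and 0.450 without the 2 distant libraries. Of the 59 genes called in IR against control, 9 were also called higher and 14 also lower in CS2164_IR against CS2164, where independent lists would share 1.06 and 1.83.

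CS2164 and IR, each against the same 3 controls, shared 10 genes called higher and 6 called lower, where independent lists would share 2.92 and 2.89, and 2 genes were called in opposite directions. With the GC and length trends removed they shared 28 and 24, where 8.62 and 19.7 would be shared by independent lists, and 21 were called in opposite directions. The 16 shared genes were 5 with the replicate block, 27 without a filter, 0 to 5 without control replicate 1, 2 or 3, CS2164 replicate 2, IR replicate 1, 2 or 3, or CS2164_IR replicate 2 or 3, and 53 without CS2164 replicate 1. Their effects correlated with r = 0.442, while 20 simulations of unchanged groups against these controls gave r = 0.498, and the covariance was 0.0796 against 0.0338. IR and CS2164_IR shared 9 genes called higher and 3 called lower, where 0.0414 and 0.0138 would be shared by independent lists, with r = 0.797 against a simulated 0.498 and a covariance of 0.112 against 0.0338. The simulated genes were drawn independently, without a trend shared by libraries. In the data the deviations of control replicates 1 to 3 had a rho with GC content of -0.332, -0.362 and -0.540. The simulations may therefore understate what shared controls give. Part or all of each excess may come from the shared controls, since 3 controls are too few to give each comparison its own.

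**Figure D5:**
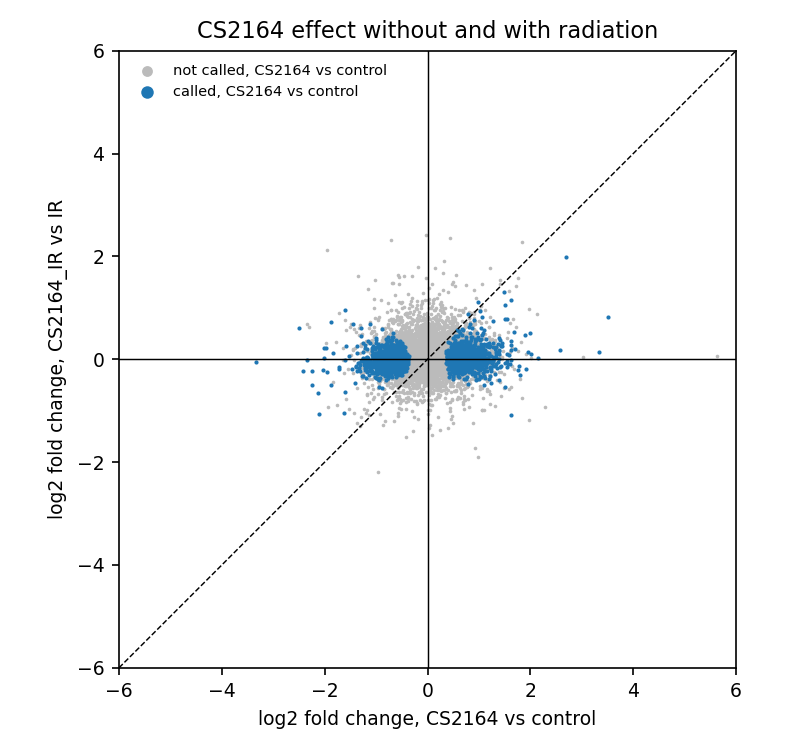
Each point is 1 of the 13521 tested genes, with the log2 change of CS2164 against control (horizontal axis) and of CS2164_IR against IR (vertical axis), and a dashed line where both are equal. The points do not follow the line: the Pearson r is 0.0829, and the genes called with CS2164 alone have a median change of 0.02 with radiation.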

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

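The tests of GC content and gene length, of the 2 distant libraries, of RNA from other cells, of the standard errors and of a shared technical state, and the averaged count for exchanged libraries, were chosen after the results were seen, and the permutation of list scores was added after the data were seen. For 3 gene lists the CS2164 effect differed between tumours without and with radiation by the camera test of the interaction. Glycolysis genes differed by a median of -0.5195 (adjusted p of 0.0296, and adjusted p = 0.994 with an estimated correlation), with a median of 0.45 without radiation and 0.03 with it. Mitochondrially encoded genes differed by 0.5584 (adjusted p of 0.00331, and adjusted p = 0.802 with an estimated correlation), with medians of -0.45 and 0.09. Fibroblast and pericyte markers differed by -0.5844 (adjusted p of 0.0296, and adjusted p = 0.367 with an estimated correlation), with medians of 0.47 and -0.01. With the GC and length trends removed the adjusted p of these lists was 0.155, 0.885 and 0.143, so none passed. Without control replicate 3 none of the 3 passed either, and without the 2 distant libraries the mitochondrial list alone of the 3 did (0.00769). The glycolysis list also did not pass without control replicate 1, CS2164 replicate 1, IR replicate 2 or CS2164_IR replicate 1 (0.0678 to 0.528), nor did the fibroblast list without control replicate 1 (0.0576).

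Between CS2164 and control 2669 genes were called, and the 10 splits of the 6 libraries are too few for a share under 0.05 (1 of 10 as large, with 2669 for the labels and 0 for the highest other). Removing the GC and length trends left 48.41% of the genes called in the same direction. The median change of all the genes called before went from 0.67 to 0.40. The median standard error over all tested genes was smaller (0.148 against 0.190). These trends are thus not the whole of the difference, and why single calls ended was not tested. Without control replicate 2 and CS2164 replicate 1 the median kept 0.6547 of its size, and all called genes kept their sign. Human markers of all other cells together took at most 0.1188% of a library. Host cells in these tumours are of mouse and mouse reads were not measured, so this share cannot decide whether RNA of other cells contributed. The rho of a library's deviation from the mean of all libraries with GC content averaged -0.411 in control. It averaged 0.125 in CS2164, 0.0701 in IR and 0.0991 in CS2164_IR. Each control library (-0.332 or lower) lay below every other library (-0.298 or higher). An effect of the inhibitor remains a hypothesis, beside a technical state of the CS2164 or the control libraries that no label records.

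By edgeR no gene was called between CS2164_IR and IR, where 331 had an unadjusted p under 0.05 and voom and DESeq2 also called 0. All 10 splits of those libraries gave 0 genes, and against a real count of 0 they say nothing on chance. With each comparison fitted to its own 6 libraries the median standard error was smaller than in CS2164 against control (ratio 0.6475), which argues against lower precision in the irradiated libraries. No other split of the 6 irradiated libraries called a gene between the groups (highest 0), but exchanging IR replicate 3 with CS2164_IR replicate 3 raised the count for CS2164 averaged over radiation from 24 to 642, as an exchanged pair would. The bound written beforehand looked at the first count alone, so an exchange of these libraries cannot be told apart from the other explanations. The fitted trends over GC content and length are not the whole of the contrast. After their removal 2175 genes were called between CS2164 and control and 0 between CS2164_IR and IR. The count of 2175 is not a like measure to that before, because the median standard error fell from 0.190 to 0.148. Of the 2669 genes called before, 1292 kept their call, and how much of the contrast the trends gave was not tested. The genes called with CS2164 alone had a median change of 0.0183 with radiation, which a dependence on radiation and a technical state shared by the 3 CS2164 libraries would both give, so these cannot be told apart without a batch label or further libraries. The test of the interaction called no gene by edgeR, with 2732 at an unadjusted p under 0.05, 0 by voom and 656 by DESeq2, so all of 100 drawn splits reach its count (highest other 150) and they say nothing on chance.

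Mitosis genes were lower with CS2164 in both strata, with medians of -0.37 without and -0.23 with radiation and -0.31 averaged, but with an estimated correlation none of these calls held (adjusted p = 0.766, 0.348 and 0.466). With the trends over GC content and length removed the averaged median was -0.2259, and with each library left out in turn it stayed at or below -0.239 (without CS2164 replicate 1), which argues against either as the whole cause. An exact two-sided permutation of the list scores within the radiation strata gave p = 0.01 (smallest possible 0.005), under the bound written beforehand, but that bound did not count the 27 lists, and over these the adjusted p was 0.054. Spread between tumours therefore cannot be told apart from an effect of the inhibitor at this number of libraries. A lower mitotic share of cells under an Aurora kinase B inhibitor is a candidate explanation, which RNA of whole tumours does not test.

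For the other comparisons of 3 against 3 libraries the 10 splits are again too few for a share under 0.05. IR against control gave 59 genes with a highest other of 0, CS2164_IR against control 26 with 2, and CS2164_IR against CS2164 1310 with 0, each with 1 of the 10 splits as large. For IR averaged over CS2164 1 of 100 splits was as large, the labelled one, which argues against chance. It gave 1030 genes, with a highest other of 642, from exchanging control replicate 2 with IR replicate 3. For CS2164 averaged over radiation 2 of 100 splits were as large (24 genes). That share is under 0.05, but the median of the other splits was 0, so a small count also reaches it. Chance was therefore not excluded for CS2164 averaged over radiation. The 1 other split as large, which exchanged IR replicate 3 with CS2164_IR replicate 3, gave 642 genes. That is a structure among the libraries that the groups do not describe and that an exchange of these 2 labels would also give.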

How the results depend on the processing

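The GC and length correction and the fit without the 2 distant libraries were chosen after seeing the data; the other alternatives were fixed beforehand. No gene examined singly reversed under any alternative. These genes were chosen because they passed in the same libraries, so a reversal was unlikely from the start and its absence is no further evidence. Of 247 passing results 245 kept their call with RLE scaling, 232 with upper-quartile scaling and 203 with the replicate block. It was kept by 200 of 245 with the GC and length correction and 199 without the 2 distant libraries. With the compared groups alone 96 of 169 kept it, and 156 to 218 with 1 library left out. Of 61 passing lists 60 kept their call with RLE scaling (all but the checkpoint list of CS2164 averaged, at an adjusted p of 0.052), 59 with the replicate block, 48 without the 2 distant libraries, 47 with the GC and length correction, 25 with fry and 3 with an estimated correlation, and 1 reversed: mitochondrially encoded genes in CS2164 against control, at 0.0464 with the GC and length correction. A 2-fold minimum asks for more and can only lower a count. Fits with the compared groups alone have fewer samples and a spread of their own, and no filter tests more genes. Fewer samples alone do not explain those fits. Their count fell from 2669 to 285 for CS2164 against control but rose from 59 to 138 for IR against control. Apart from the 2-fold minimum, the cause of the differences was not tested. Replicate numbers showed little sign of pairing the libraries. Same-number libraries of different groups correlated at -0.372 to 0.149 after removal of group means, with 3 of 18 pairs above 0.1. This cannot show that animals or batches were not paired by number, and the labels do not say. Depth limits genes below about 0.178 to 0.233 CPM.

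With the replicate block the gene counts were 20 for IR against control and 4 for CS2164 averaged, and 5 genes were shared by both single treatments. Upper-quartile scaling gave 13 for CS2164 averaged. Without a filter the counts were 117 for IR against control, 96 for CS2164_IR against control, 333 for CS2164 averaged and 60 for the interaction, the shared genes were 27, and the correlation across genes was -0.0221 for the CS2164 effect without and with radiation, a reversal, and 0.0908 for the IR effect without and with CS2164. Voom gave 22 for IR against control and 13 for CS2164 averaged. DESeq2 gave 340 for IR against control, 316 for CS2164_IR against control, 1015 for CS2164 averaged, 1558 for IR averaged and 656 for the interaction. A 2-fold minimum gave 320 for CS2164 against control, 32 for IR against control, 192 for CS2164_IR against CS2164, 1 for CS2164 averaged and 110 for IR averaged. The compared groups alone gave 285, 138, 13 and 834 for CS2164, IR and CS2164_IR against control and CS2164_IR against CS2164.

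The GC and length correction gave 351 for IR against control, 296 for CS2164_IR against control, 2537 for CS2164_IR against CS2164, 504 for CS2164 averaged, 2555 for IR averaged, 67 for the interaction and 52 shared genes, with a correlation of 0.3463 for the IR effect. Its passing lists were 2 for CS2164 against control, 6 for CS2164 averaged and 0 for the interaction. Without the 2 distant libraries the counts were 963 for CS2164 against control, 445 for IR against control, 417 for CS2164_IR against control, 3265 for CS2164_IR against CS2164, 340 for CS2164 averaged, 3680 for IR averaged and 162 for the interaction, and the IR effect correlated at 0.4504. With an estimated correlation the passing lists were 0 for CS2164, IR and CS2164_IR against control, for CS2164_IR against CS2164, for CS2164 averaged and for the interaction, 1 for CS2164_IR against IR and 2 for IR averaged. With fry they were 5 for CS2164_IR against control, 1 for CS2164_IR against IR, 3 for CS2164_IR against CS2164, 3 for CS2164 averaged and 0 for the interaction.

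With each library left out in turn the gene counts ranged from 621 (without control replicate 2) to 2665 for CS2164 against control, 0 (IR replicate 1) to 458 (CS2164 replicate 1) for IR against control, 0 (control replicates 2 and 3) to 436 (CS2164 replicate 1) for CS2164_IR against control, 0 to 1 (CS2164_IR replicate 2) for CS2164_IR against IR, 310 (CS2164_IR replicate 3) to 2049 (control replicate 2) for CS2164_IR against CS2164, 0 to 432 (control replicate 1) for CS2164 averaged, 445 (IR replicate 1) to 2397 (CS2164 replicate 1) for IR averaged and 0 to 1 (control replicate 2) for the interaction. The shared genes ranged from 0 (IR replicate 1) to 53 (CS2164 replicate 1). The correlation ranged from -0.0517 (IR replicate 1) to 0.1458 (IR replicate 3) for the CS2164 effect and 0.1218 (IR replicate 1) to 0.3462 (CS2164 replicate 1) for the IR effect. The passing lists ranged from 3 (control replicate 3) to 6 for CS2164 against control, 7 (CS2164_IR replicate 1) to 14 for CS2164_IR against IR, 6 (CS2164 replicate 1) to 12 for CS2164 averaged, 5 (CS2164_IR replicate 1) to 11 for IR averaged and 0 (control replicate 3) to 7 (control replicate 2) for the interaction.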

Other observations

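The permutation of list scores was added after the data were seen, as was the margin for leaving out 1 library from the hepatocyte list. Interferon-stimulated genes did not pass as a list with CS2164 alone (3 of 42 rose, OAS3, an antiviral sensor, by 0.76 ± 0.16, and 1 fell; adjusted p of 0.452) or with IR alone (1 fell; adjusted p of 0.111). Of 20 MHC class I genes TAPBP, which loads peptides, rose by 1.28 ± 0.20 with CS2164 alone, 2 fell, and the list did not pass (adjusted p of 0.691), nor did it with IR (adjusted p of 0.489). Of 18 fetal liver and liver cancer markers 3 rose, SPINK1 among them, and 4 fell, IGF2 among them, with IR averaged over CS2164 (adjusted p of 0.675). AFP, the fetal liver marker, stood at 18675 ± 2894 CPM in control, 14190 ± 4115 in CS2164, 12943 ± 2392 in IR and 16608 ± 2820 in CS2164_IR.

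Of 32 apoptosis regulators 3 rose and 5 fell with CS2164 alone, with TNFRSF10A, a death receptor, rising by 1.01 ± 0.295 (list adjusted p of 0.452). HRK, an activator of cell death, rose by 1.55 ± 0.46 with IR averaged over CS2164. Of the 24 members of the angiogenesis list, which holds receptors and inhibitors of vessel growth too, 4 rose with CS2164 alone and 4 with IR averaged, without the list passing (adjusted p of 0.452 and 0.178). Of 5 lymphoid markers tested none passed in CS2164 or IR against control (list adjusted p of 0.933 and 0.604), none of the 4 tested endothelial markers passed in those comparisons, and no erythroid marker had enough counts to be tested. Of the kinase targets, 2 were tested: AURKB, described above, and PDGFRA, at 9.70 ± 0.897, 11.2 ± 1.84, 14.3 ± 3.35 and 14.8 ± 3.20 CPM in control, CS2164, IR and CS2164_IR, which did not pass in any comparison.

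In the exact two-sided permutation of list scores within strata, whose smallest p is 0.005, 7 of the 27 lists had p under 0.05 for CS2164 averaged over radiation and 9 for IR averaged over CS2164. None passed after adjustment over the lists (lowest adjusted p 0.054 and 0.0675). Over 27 lists, even a list at the smallest p passes only if enough others are also low. Not passing here is therefore no evidence against a list. For IR the histone and cholesterol scores reached the smallest p, with differences of 0.54 and -0.22. The higher hepatocyte list in CS2164_IR than in IR (median 0.3763) was 0.2001 without CS2164_IR replicate 1, so whether this 1 library carries it cannot be told from 3 libraries.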
